A study of Mus musculus with 26 samples.

How the data were processed

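The data were bulk RNA sequencing libraries of stromal cells sorted from the hearts of C57BL/6 mice that carry a nuclear green fluorescent protein (GFP) under the control of Pdgfra, the gene of platelet-derived growth factor receptor alpha. Per the labels, the cells were negative for CD45 (leukocytes) and CD31 (endothelium), positive for GFP, and split by SCA-1, the surface protein encoded by Ly6a. Hearts were undamaged or taken 7, 14 or 28 days after ligation of the left anterior descending coronary artery. Libraries were made with a stranded mRNA kit and sequenced as paired ends, per the labels.

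The deposited values were counts, whole numbers of reads per gene for each library, as a table with 24421 genes plus 2 entries that name no gene: reads outside every gene and reads shared by several genes. Per the submitters' processing notes the tools were bcl2fastq, TopHat, Bowtie2, STAR and Cufflinks with the mm10 build, with no versions. The program that counted the reads, its strand setting and its annotation were not given in the sources used here. Genes were therefore read by the symbol in the table, and 23376 symbols (95.7%) were found in GENCODE M21, which gave identifiers and GRCm38 positions. Symbols of related (Ly6a with Ly6c1) or near-identical paralogs (Hspa1a with Hspa1b) and of overlapping or adjacent genes (Duox1 with Duoxa1) can share reads in such counts. The deposited counts carry no molecular identifiers, so PCR copies are counted and intervals or floors cover counting error only. Reads outside genes were 5.53% to 18.7% of each library, except for 55.8% in the Sca-1 positive day 28 replicate E2, and reads shared by several genes were 0.128% to 0.646%.

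Groups came from the labels. Of the 6 day 7 libraries, 4 carry no gate in their labels and were never assigned one. The labels do not say which libraries came from separate animals, so every p measures the spread between these libraries. The replicate codes in the titles fall into 2 families: a letter with a digit, here called letter-coded, and the same kind of code after a number, here called prefixed. Each number directly before a code occurs at a single time point. Fits on prefixed libraries alone therefore do not hold this number constant between time points. Where one code occurs in both gates of a time point (7 such pairs), the deviations of the pair from their group means correlated at r = 0.187 to 0.412 across 13812 genes, and each library correlated best with its own code. Day 14 adds little to this, since with 2 libraries per gate its values are mirrored (0.412 for own, -0.412 for other codes). Outside it, libraries of separate codes correlated at -0.371 to -0.0654 across the families and at 0.0512 to 0.394 within a family, so part of the correlation follows the family. As each pair was above 0.1, the codes were treated as pairs. For the gate comparisons and their interactions a fit with the code as a block was run beside the fit without it. Comparisons between time points had no such fit, so their p treat libraries that share a code as independent. Genes are not independent replicates in these correlations.

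Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM factors, a low-count filter on the groups, quasi-likelihood fits and two-sided tests, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested as the threshold for a call. The gated fit held 20 libraries in 6 groups and 13812 genes, with the day 7 libraries left out. The day 14 groups of 2 libraries borrowed their spread from the other groups. The time fit held 26 libraries, 13392 genes and 4 time points without the gate. A higher or lower count below means calls in that direction. The gates at day 7 have 1 library each and were described without a test, as log2 ratios of CPM (counts scaled to one common library total) after adding 0.5 CPM, with list medians placed among 10000 random lists of matched expression. Values after ± are standard errors for log2 differences and SD for CPM. Fitted differences of genes near 0 counts in one group depend on the prior count of the fit, so levels are given with them.

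The 27 gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over the lists of a comparison. The plan also held fry, which asks whether the genes of a list move without comparing them with other genes. Its values are given below only for some gate differences with the code pairs as a block. Between 24 and 25 lists could be tested, since lymphoid and erythroid markers had 1 measured member each. Both counts of called members are given, over all genes and adjusted over the list alone. Genes to be named were fixed as 16 anchor genes, up to 8 genes per direction with the largest change (mean log2 CPM of at least 3, no overlap between the libraries compared, no predicted models), and the 4 members of each list with the smallest p. Of the genes this rule gave, those whose sign held and whose call few settings or left-out libraries changed were preferred for the text, a choice made after their values were seen. The comparisons, rule, lists and most alternatives were written down before the data were examined.

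On simulated counts with the design and spread of these data, genes changed 2-fold were recovered at 44.8% for the gate in undamaged hearts, 7.46% at day 14 and 19.4% at day 28. For a 4-fold change these shares were 65.2%, 47.0% and 65.2%. Against undamaged hearts, 49.3% (day 14), 65.7% (day 28) and 53.7% (day 7) of genes changed 2-fold were recovered, and 78.8%, 83.3% and 90.9% at 4-fold. For day 28 against day 14 the recovered shares were 44.8% and 74.2%, for day 14 against day 7 they were 43.3% and 77.3%, and for both interactions at most 1.49% and 43.9%. The simulated counts were drawn independently, without correlation between genes or between libraries of a code or family. Under that assumption at most 9.38% of the calls in one simulated comparison were false. A list moved 1.5-fold was found at an adjusted p of 2.85e-16 by camera at the preset correlation, and none of the unmoved lists was called. As these genes were independent, this says nothing of false list calls where genes correlate.

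Alternatives were other size factors, no or a stricter low-count filter, DESeq2 1.42.0, limma-voom, a test for changes beyond 1.5-fold (glmTreat), fits on only the groups compared, the code block, the code family as a covariate, each family alone, and leaving out each library in turn. Added after seeing the data were fits without the 3 undamaged libraries with fewest detected genes, without the library with most reads outside genes, without the libraries with Xist above 20 CPM, and some fits within a code family or against undamaged libraries of a single family.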

Results

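The series holds 26 libraries of Pdgfra-GFP positive cardiac stromal cells, sorted free of CD45 and CD31 positive cells and split by SCA-1. Undamaged hearts gave 5 Sca-1 positive libraries (15.5 to 22.3 M, or mega, counts assigned to genes each) and 4 Sca-1 negative ones (10.9 to 15.2 M). Day 7 after coronary ligation gave 1 library of each gate (14.9 M positive, 14.2 M negative) and 4 whose gate the labels do not give (10.9 to 19.1 M). At day 14 there were 2 positive (19.8 and 48.8 M) and 2 negative libraries (19.6 and 45.4 M). At day 28 there were 4 positive (6.79 to 17.6 M) and 3 negative ones (10.7 to 15.6 M). At these depths 3 counts in a library correspond to 0.0583 to 0.416 CPM. Xist, a transcript of the inactive X chromosome, was above 20 CPM in 6 libraries, 4 at day 7 and 2 at day 14.

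Ly6a, the gene of the sorted SCA-1 protein (ENSMUSG00000075602.10, GRCm38 chromosome 15, 74994877 to 74998031), separated the gates at each time. It averaged 676 ± 410.0 CPM in the positive and 52.6 ± 37.6 in the negative gate of undamaged hearts, 511 ± 52.5 and 72.8 ± 15.6 at day 14, and 349 ± 55.6 and 42.0 ± 15.6 at day 28. The single day 7 libraries held 297 (positive) and 30.7 CPM (negative). The day 7 libraries 1A, 1B, 4A and 4B, whose gate is not given, held 297, 36.1, 329.9 and 31.2 CPM. Pdgfra, which drives the sorted GFP, averaged 610.2 ± 86.1 and 574 ± 106.3 CPM in the positive and negative gates of undamaged hearts, 519 ± 70.05 and 484 ± 157 at day 14, and 638 ± 136 and 567 ± 61.7 at day 28. Ptprc, the gene of the CD45 protein used to exclude leukocytes, averaged between 0.291 ± 0.335 (undamaged, n = 9) and 1.12 ± 0.633 CPM (day 7, n = 6) over the 4 time points.

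The first question was how the gates differ in undamaged hearts (5 positive against 4 negative libraries). Adventitial progenitor genes, which mark fibroblasts around vessels and in fascia, were higher in the positive gate. Of 28 measured members 18 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 6.91e-52, and 0.000285 with an estimated correlation). Sema3c, a secreted semaphorin (ENSMUSG00000028780.13, chromosome 5, 17574281 to 17730268), was higher by 3.23 ± 0.23 log2 (adjusted p = 1.88e-07; 222 ± 33.3 against 23.7 ± 4.00 CPM). Dpp4, a cell-surface peptidase (ENSMUSG00000035000.8, chromosome 2, 62330073 to 62412231), was higher by 3.81 ± 0.38 (adjusted p = 7.97e-06; 64.5 ± 14.5 against 4.60 ± 1.504 CPM). The chemokine scavenging receptor Ackr3 (2.19 ± 0.20), the microfibril protein Mfap5 (1.54 ± 0.16), Efhd1 (4.28 ± 0.47), Cd55 (1.96 ± 0.21), Pi16 (1.89 ± 0.27) and Thy1 (2.27 ± 0.37) rose as well, at adjusted p between 4.48e-06 and 0.00124. Among genes outside the list, the hydrogen peroxide producing oxidase Duox1 averaged 31.6 ± 13.6 against 0.354 ± 0.477 CPM (adjusted p = 1.51e-05). Cmah, an enzyme of sialic acid synthesis, averaged 18.9 ± 7.32 against 0.378 ± 0.365 CPM (0.235 without replicate F3; adjusted p = 1.78e-05). Cadm3 (6.04 ± 0.63) and Ly6c1 (3.33 ± 0.55) were also higher.

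In the negative gate of undamaged hearts, Wif1, a secreted Wnt inhibitor (ENSMUSG00000020218.11, chromosome 10, 121033960 to 121100650), averaged 101.3 ± 84.1 CPM (60.5 without replicate A6, which held 224) against 9.38 ± 6.02 in the positive gate (log2 difference -3.43 ± 0.50, adjusted p = 0.000458). The mural markers, genes of pericytes and smooth muscle, were lower in the positive gate, with 4 of 12 called (0 higher and 9 lower adjusted over the list alone). Their adjusted p was 3.57e-11, and 0.00646 with an estimated correlation, which became 0.0768 with the code pairs as a block. By fry with that block their adjusted p was 0.0255. Their member Notch3, a receptor of mural cells, averaged 31.9 ± 7.17 CPM in the positive and 159.9 ± 67.4 in the negative gate (-2.32 ± 0.30, adjusted p = 0.000122). Fmod, a small collagen-binding proteoglycan, differed by -2.79 ± 0.51. Apba2 (-2.68 ± 0.46), Kcnip1 (-2.56 ± 0.48), Mrvi1 (-2.49 ± 0.23) and Bmp4 (-0.88 ± 0.13) were lower too. Lipid handling genes had 3 of 20 members lower (6 adjusted over the list alone; adjusted p = 0.000361, and 0.116 with an estimated correlation). Matrifibrocyte genes, which encode cartilage, tendon and bone matrix proteins, had 4 of 24 lower (2 higher and 6 lower adjusted over the list alone; adjusted p = 0.0269, and 0.902 with an estimated correlation). With the code pairs as a block, lipid handling genes had an adjusted p of 0.0768 with an estimated correlation and 0.0255 by fry. Without the 3 undamaged libraries with fewest detected genes, edgeR called 0 lipid and 0 matrifibrocyte genes lower. The list medians were -0.69 and -0.04 log2 there, so the lipid difference remained while its calls went.

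Proliferation genes had 2 of 35 higher in the positive gate of undamaged hearts (2 adjusted over the list alone; adjusted p = 0.00311). Interferon response genes had 1 of 35 (1 adjusted over the list alone; adjusted p = 0.00217). Both calls were lost with an estimated correlation (adjusted p = 0.902 with an estimated correlation for each) and with the code pairs as a block (0.0835 and 0.366). Matricellular genes had 4 higher and 2 lower of 26 (6 and 2 adjusted over the list alone), among them Fn1, the gene of fibronectin (2.37 ± 0.44, adjusted p = 0.0041), without a call for the list (adjusted p = 0.122). Wnt pathway genes had 3 higher and 1 lower of 29 (5 and 4 adjusted over the list alone; adjusted p = 0.256). Collagens had 1 higher, Col14a1 (1.26 ± 0.22), and 1 lower of 19 (adjusted p = 0.353). TGF-beta and BMP pathway genes had 1 higher, Fstl1 (1.07 ± 0.18), and 1 lower, Bmp4, of 30 (adjusted p = 0.806). The lists of collagen processing, contractile, cardiac fibroblast identity, chemokine, complement, matrix protease, glycolysis, oxidative phosphorylation and early response genes had adjusted p between 0.0536 and 0.961. So did the markers of endothelium, macrophages, cardiomyocytes, Schwann cells, epicardium and adipocytes. Of these, macrophage markers, with 0 of 15 members called by edgeR and 1 higher by DESeq2, had an adjusted p of 0.0169 with the code pairs as a block, and 0.584 with an estimated correlation.

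By edgeR, 228 genes were higher and 200 lower in the positive gate of undamaged hearts (2231 at an unadjusted p under 0.05, where 690.6 are expected by chance). The count was 265 without replicate E1, 268 without E3 and 273 without F3 of the positive gate. Within the letter-coded libraries 284 were higher and 319 lower, and within the prefixed ones 167 and 45. In the latter Apba2 (-2.89, adjusted p = 0.109), Kcnip1 (-1.93, 0.0728), Notch3 (-1.63, 0.0775), Fn1 (1.54, 0.207), Bmp4 (-0.77, 0.0827), Fstl1 (0.74, 0.173), Col14a1 (0.91, 0.177) and Cd34 (1.07, 0.0790, from 1.07 ± 0.20 and 0.0044 with all libraries) were no longer called. Wif1 was not called in the letter-coded ones (-2.20, adjusted p = 0.0622). Fmod was not called without the 3 libraries with fewest detected genes (-1.83, 0.161).

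**Figure D1:**
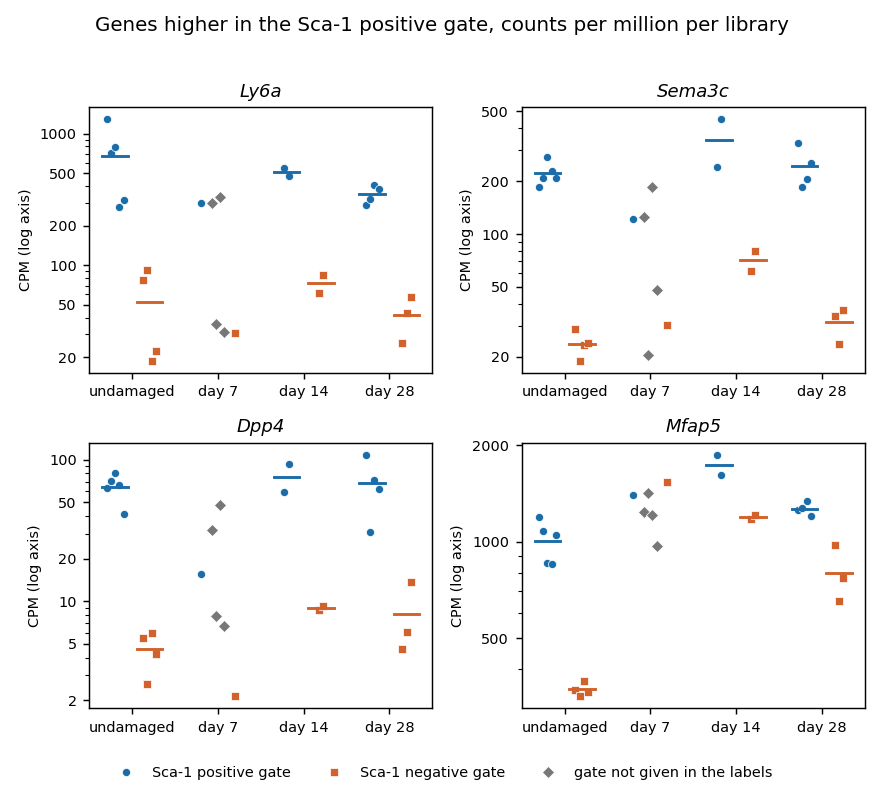
CPM (log axis) of Ly6a, Sema3c, Dpp4 and Mfap5 in each library by time and gate, with lines at group means; gray diamonds are the 4 day 7 libraries without a labelled gate. Sema3c averaged 222 against 23.7 CPM in undamaged hearts, and Mfap5 in the negative gate rose from 346 to 800.5 CPM by day 28.

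At day 14 the same contrast had 2 libraries per gate. Adventitial progenitor genes were again higher in the positive gate, with 3 of 28 called over all genes and 18 adjusted over the list alone (0 lower; adjusted p = 6.04e-69, and 4.74e-05 with an estimated correlation). Sema3c (2.28 ± 0.32, adjusted p = 0.00818; 345 ± 149 against 70.8 ± 13.5 CPM), Dpp4 (3.08 ± 0.51, 0.0187) and Ackr3 (1.77 ± 0.29, 0.0169) were those members. Tmem100 (2.67 ± 0.39, adjusted p = 0.00818), Cmah (4.95 ± 0.80, 0.0169) and, named after their values were seen, Duoxa1 (4.02 ± 0.65) and Xpnpep2 made up the 7 genes called higher. No gene was lower. At an unadjusted p under 0.05 there were 257 genes, fewer than the 690.6 expected by chance. DESeq2 called 29 higher and 4 lower and limma-voom 20 and 5. Ly6a differed by 2.81 ± 0.71 and did not pass (adjusted p = 0.437), but passed with DESeq2 (0.0300) and with the code pairs as a block (2.82, 0.000594).

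Other lists moved at day 14 by the preset test, without a member called over all genes by DESeq2 or by edgeR without the code block. Matrifibrocyte genes were lower in the positive gate (adjusted p = 8.29e-10, and 0.0679 with an estimated correlation). So were epicardial (0.000422, 0.381), mural (0.000845, 0.268) and contractile genes (0.0107, 0.421). The latter of each pair is the adjusted p with an estimated correlation. Interferon (8.72e-05, 0.671), complement (0.000196, 0.381), chemokine (0.014, 0.769), cardiac fibroblast identity (0.0161, 0.381) and matrix protease genes (0.0464, 0.69) were higher. Adjusted over the list alone, 1 complement gene was higher and 1 mural gene lower among these. With the code pairs as a block, 40 genes were higher and 12 lower and 12 adventitial genes were called. Members of the lists above were then called too, such as mural Notch3 (-1.62, adjusted p = 0.00686), complement Cfb (2.46, 0.00542) and chemokine list member Ptx3 (2.24, 0.0150). The blocked list tests also called collagens (lower, adjusted p = 0.0276, and 0.817 with an estimated correlation) and matricellular genes (lower, 0.00207, and 0.445 with an estimated correlation). The complement and epicardial calls then held with an estimated correlation (adjusted p = 0.0316 and 0.0435). No gene was called without the negative replicates D1 or D9 or the positive replicate D9. There were 4 without the positive replicate D1, where Cmah (4.98, adjusted p = 0.0532) and Ackr3 (1.90, 0.0525) missed the threshold.

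At day 28, with 4 positive and 3 negative libraries, 9 of 28 adventitial progenitor genes were higher in the positive gate (17 adjusted over the list alone, 0 lower; adjusted p = 6.46e-27, and 0.00675 with an estimated correlation). Sema3c was higher by 2.97 ± 0.26 (adjusted p = 7.11e-06; 244 ± 64.4 against 31.5 ± 6.92 CPM), Dpp4 by 3.07 ± 0.42 (0.0011), Efhd1 by 3.09 ± 0.51 (0.00515), Ackr3 by 1.66 ± 0.23 (0.0011) and Cd55 by 1.62 ± 0.24 (0.00239). Duox1 (4.80 ± 0.72) and Cmah (4.78 ± 0.69) were higher as well, and Ly6a was by 3.07 ± 0.57 (adjusted p = 0.0129). Notch3 (-2.18 ± 0.34, adjusted p = 0.00366) and Msc, a bHLH transcription factor (-1.70 ± 0.26, 0.00239), were lower. Lipid handling genes had 1 of 20 lower (5 adjusted over the list alone; adjusted p = 0.000149, and 0.113 with an estimated correlation). Mural markers had 1 of 12 (2 adjusted over the list alone; 0.00115, and 0.287 with an estimated correlation), and matrifibrocyte genes 0 of 24 by edgeR (4 lower by DESeq2, 3 without the 3 undamaged libraries with fewest genes, 4 adjusted over the list alone; 0.000255, and 0.363 with an estimated correlation). Early response genes (lower, adjusted p = 0.00115), proliferation (higher, 0.0221), interferon (higher, 0.0318), glycolysis (lower, 0.0318) and epicardial genes (lower, 0.0318) had no member called by edgeR or DESeq2. All 5 calls were lost (adjusted p = 0.71 with an estimated correlation).

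In all, edgeR called 60 genes higher and 22 lower at day 28 (2027 at an unadjusted p under 0.05), with 21 and 4 in the prefixed libraries alone, where Notch3 missed the threshold (-2.31, adjusted p = 0.0675). The count was 18, 26 and 44 without the negative replicates B4, B6 and E4, each of which ended the call of Ly6a (3.09, adjusted p = 0.106; 3.35, 0.0580; 2.81, 0.0918). It was 53 and 155 without the positive replicates E2 and B4, and 129 without the undamaged negative replicate B7. Duox1 and Cmah were not called by limma-voom. With the code pairs as a block, the matrifibrocyte gene Fmod was called lower (-2.07, adjusted p = 0.0153). The blocked list tests also called chemokine (higher, adjusted p = 1.7e-07) and complement genes (higher, 2.1e-06), at 0.231 and 0.171 with an estimated correlation. By fry with this block complement, lipid handling and epicardial genes had an adjusted p of 0.0477 each. Chemokine and mural genes had 0.168 each and matrifibrocyte genes 0.215 by fry.

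Gate differences kept their direction over time. Of the 428 genes called in undamaged hearts, 412 (96.3%) had the same sign at day 14 and 405 (94.6%) at day 28, against 66.5% and 63.4% of all genes. The undamaged and day 28 calls, from separate libraries, shared 47 higher genes where 0.990 was expected by chance and 18 lower ones where 0.319 was expected. Of them 0 had opposite directions. Called higher at all 3 times were Sema3c, Dpp4, Ackr3, Cmah, Tmem100 and Duoxa1. In the single day 7 libraries 315 of 401 of these genes (78.6%) had the sign of the undamaged difference, 180 of 220 higher and 135 of 181 lower ones, where 52.9% of all 12294 genes were above 0. The adventitial progenitor list had a median log2 ratio of 0.835 there (26 of 28 members above 0), above all 10000 random lists. So were the medians of complement (0.926), chemokine (0.561), interferon (0.518) and cardiac fibroblast identity genes (0.381). Collagen (-0.390), matricellular (-0.480), contractile (-0.375), matrifibrocyte (-0.645) and epicardial genes (-1.42) had medians below all random lists. These come from 1 library per gate, without a test.

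The change of the gate difference after ligation was tested as an interaction. Mfap5 averaged 1007 ± 148 CPM in the positive and 346 ± 16.6 in the negative gate of undamaged hearts, 1739.6 ± 176 and 1197 ± 24.4 at day 14, and 1266 ± 54.3 and 800.5 ± 165 at day 28. Its interaction was -1.01 ± 0.27 at day 14 (adjusted p = 1) and -0.87 ± 0.23 at day 28 (0.907). That of Ly6a was -0.87 ± 0.80 and -0.61 ± 0.67 (1 and 0.919). By edgeR 0 genes were called at either time (202 and 719 at an unadjusted p under 0.05, where 690.6 are expected by chance). DESeq2 called 2 higher at day 14 and 3 higher and 1 lower at day 28. At day 14 the list tests called the interaction downward for adventitial (adjusted p = 4.07e-05, and 0.35 with an estimated correlation), matricellular (0.000444, 0.506), proliferation (1.8e-06, 0.321) and macrophage genes (2.84e-05, 0.35). They called it upward for lipid (2.84e-05, 0.0753) and mural genes (3.97e-06, 0.0753), the latter of each pair again with an estimated correlation. From undamaged hearts to day 14 the median gate difference moved toward 0 in adventitial (1.64 to 1.18 log2), mural (-1.40 to -0.48) and lipid genes (-0.63 to -0.04). In the prefixed undamaged libraries alone these medians were 1.26, -1.48 and -0.46. All day 14 libraries are prefixed, so within this family the adventitial median moved only from 1.26 to 1.18. The median gate difference changed sign in matricellular (0.24 to -0.30), although it was -0.02 in the prefixed undamaged libraries alone, and in proliferation genes (0.75 to -0.12). Macrophage genes went from 1.24 to -0.45, but the former was 0.10 without the 3 undamaged libraries with fewest genes and 0.07 in the letter-coded libraries alone. At day 28, 6 lists were called and none with an estimated correlation (adjusted p of at least 0.558). They were adventitial (6.73e-05), macrophage (6.73e-05), oxidative phosphorylation (0.00289), early response (0.00414) and collagen processing genes (0.0421) downward and mural genes (0.00911) upward. Blocking by code pairs ended the calls of oxidative phosphorylation (0.296) and collagen processing (0.833). It added chemokine (0.0054, and 0.651 with an estimated correlation) and complement genes (0.0427, and 0.621 with an estimated correlation) at day 28 and complement (7.4e-06, and 0.152 with an estimated correlation) at day 14.

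The next question was how the cells changed after ligation. At day 7 (6 libraries against 9 undamaged, gate not in the model), matrix genes rose. Cthrc1, a secreted protein of remodeling matrix (ENSMUSG00000054196.7, chromosome 15, 39076932 to 39087121), went from 1.39 ± 0.78 to 503 ± 223 CPM (8.47 ± 0.41 log2, adjusted p = 5.82e-14). Col1a1, a chain of type I collagen (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042), went from 4011 ± 539 to 30755 ± 6603 CPM (2.94 ± 0.19, adjusted p = 1.28e-11). Of 19 collagens 16 rose and 0 fell, such as Col3a1 (2.62 ± 0.15), Col1a2 (2.59 ± 0.17) and Col5a2 (2.46 ± 0.17). Of 26 matricellular genes 22 rose and 1 fell, such as Postn, the gene of periostin (3.75 ± 0.45; 857 ± 641 to 11507 ± 3578 CPM), Wisp1 (6.97 ± 0.59), Ddah1 (6.42 ± 0.41) and Sparc (2.04 ± 0.15). Collagen processing enzymes rose in 15 of 21, among them P4ha3 (6.32 ± 0.46), Lox (3.25 ± 0.26) and Plod2 (2.14 ± 0.19). Contractile genes, markers of myofibroblasts, rose in 12 and fell in 2 of 22, with Palld (4.52 ± 0.32), Actn1 (2.37 ± 0.18), Csrp2 (1.91 ± 0.16) and Acta2, smooth muscle actin (2.39 ± 0.30; 41.6 ± 12.2 to 218 ± 132 CPM), among the former. Counts adjusted over the list alone were the same for these 4 lists. Their adjusted p were 4.35e-35, 9.58e-28, 1.92e-15 and 1.31e-10, and 0.000886, 0.000886, 0.0217 and 0.0217 with an estimated correlation.

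Proliferation genes rose in 24 of 35 at day 7 (25 and 1 lower adjusted over the list alone; adjusted p = 2.31e-12, and 0.0699 with an estimated correlation), from low levels. Mki67 went from 1.46 ± 1.34 to 15.5 ± 5.80 CPM (3.39 ± 0.70), with Kif23 (2.95 ± 0.59), Bub1b (2.38 ± 0.35) and Plk1 (2.35 ± 0.48). Matrifibrocyte genes rose in 15 and fell in 2 of 24 (17 and 4 adjusted over the list alone; adjusted p = 3.82e-06, and 0.157 with an estimated correlation), including the transcription factor Runx1 (4.32 ± 0.34) and Comp, a cartilage matrix protein (2.51 ± 0.38). Of 23 tested, 14 were higher against letter-coded and 8 against prefixed undamaged libraries. Wnt pathway genes rose in 9, with Sfrp2 (2.90 ± 0.35) and Sfrp1 (1.43 ± 0.20), and fell in 3 of 26 (10 and 5 adjusted over the list alone; adjusted p = 0.0254, and 0.237 with an estimated correlation). Wif1 went from 50.2 ± 70.8 (28.5 without the negative A6) to 0.420 ± 0.767 CPM (-6.88 ± 1.09, not called by limma-voom). Matrix proteases and their inhibitors rose in 10, with Adam12 (4.57 ± 0.34) and Adamts12 (1.99 ± 0.29), and fell in 4 of 25 (10 and 4 adjusted over the list alone; adjusted p = 0.00824, and 0.245 with an estimated correlation).

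Genes of cardiac fibroblast identity fell in 11 of 26 at day 7 (1 higher and 13 lower adjusted over the list alone; adjusted p = 5.71e-06, and 0.0352 with an estimated correlation). Gsn, the gene of gelsolin, went from 44737 ± 6361 to 15809 ± 4959 CPM (adjusted p = 4.55e-06). The proteoglycan Dcn fell by 1.00 ± 0.15, Abca8a by 1.12 ± 0.16 and the fibroblast transcription factor Tcf21 by 0.92 ± 0.21. Lipid handling genes fell in 8 and rose in 2 of 20 (10 and 2 adjusted over the list alone; adjusted p = 0.00676, and 0.245 with an estimated correlation), with Fabp4 (-2.10 ± 0.36) among the former and Angptl4 (2.22 ± 0.40) among the latter. Lipid handling genes fell in 8 against letter-coded and 4 against prefixed undamaged libraries. Oxidative phosphorylation genes fell in 7 of 26 (7 adjusted over the list alone; adjusted p = 0.000186, and 0.333 with an estimated correlation), in 2 against letter-coded and 9 against prefixed libraries, and in 3 without the 3 undamaged libraries with fewest genes. Early response genes fell in 6, with Hspa1b (-2.35 ± 0.37), and rose in 2 of 26 (6 and 2 adjusted over the list alone; 0.00824, and 0.585 with an estimated correlation). They fell in 9 and rose in 0 against letter-coded undamaged libraries (median -0.49 log2), and fell in 2 and rose in 4 against prefixed ones (median -0.02). Adventitial genes fell in 4, with Efemp1 (-2.34 ± 0.48), and rose in 1 of 28 (4 and 1 adjusted over the list alone; 0.00824, and 0.602 with an estimated correlation). The methyltransferase Inmt (-2.95 ± 0.43) and the oxidase Aox3 (-2.51 ± 0.44) fell too.

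Markers of other cells moved at day 7. Endothelial markers fell in 13 of 15, as in Pecam1, the gene of the CD31 protein used for exclusion (38.3 ± 10.6 to 7.57 ± 2.76 CPM, -2.33 ± 0.37), and Cdh5 (-2.23 ± 0.40). Another 2 rose, including the transcription factor Erg (3.66 ± 0.43; 13 and 2 adjusted over the list alone; adjusted p = 0.000186, and 0.245 with an estimated correlation). Against prefixed undamaged libraries 6 endothelial markers fell. Epicardial and mesothelial markers rose in 10 of 13 (10 and 1 lower adjusted over the list alone; adjusted p = 1.54e-05, and 0.154 with an estimated correlation), with Wt1 from 0.813 ± 0.700 to 14.1 ± 12.1 CPM and Upk1b from 0.0800 ± 0.176 to 6.19 ± 5.59 CPM. Macrophage markers rose in 7 of 14 (9 adjusted over the list alone; adjusted p = 0.000186, and 0.237 with an estimated correlation). They rose in 0 when libraries with Xist above 20 CPM were left aside and in 1 against prefixed undamaged libraries. Among mural markers 2 rose, including Rgs4 (3.20 ± 0.41), and 1 fell of 11 (3 and 2 adjusted over the list alone; adjusted p = 0.615). Cardiomyocyte markers fell in 2 of 14 (1 adjusted over the list alone; 0.0624) and Schwann cell markers in 1 of 4 (0.385). TGF-beta and BMP pathway genes rose in 5, such as Tgfb3 (1.87 ± 0.18) and Gdf6 (1.16 ± 0.17), and fell in 6 of 29 (adjusted p = 0.743). Chemokine genes rose in 6, with Il1rl1 (5.37 ± 0.87), and fell in 4 of 29 (0.524). Interferon (1 and 5 of 35, 0.611), complement (2 and 3 of 14, 0.177) and glycolysis genes (1 and 4 of 18, 0.238) were not called. Against letter-coded and prefixed undamaged libraries, respectively, interferon genes had 1 higher and 11 lower, and 6 and 1. Chemokine genes had 2 and 5, and 8 and 1. Complement genes had 1 and 6, and 1 and 1, and glycolysis genes 0 and 6, and 2 and 1.

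By edgeR 1545 genes were higher and 1503 lower at day 7. With only the 2 day 7 libraries of a labelled gate the counts were 741 and 455, and Tcf21 (-0.74, adjusted p = 0.223), Pecam1 (-1.85, 0.0639) and Wt1 (2.20, 0.0967) were not called. Without the libraries with Xist above 20 CPM, which include 4 of the 6 at day 7, they were 603 and 277. Abca8a (-0.83, 0.0544) and Cdh5 (-2.03, 0.0950) were then not called. The lists then had 12 proliferation, 8 matrifibrocyte, 6 epicardial, 4 Wnt pathway and 3 matrix protease genes higher, and 5 identity, 2 lipid handling, 2 endothelial, 1 adventitial and 0 oxidative phosphorylation genes lower.

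**Figure D2:**
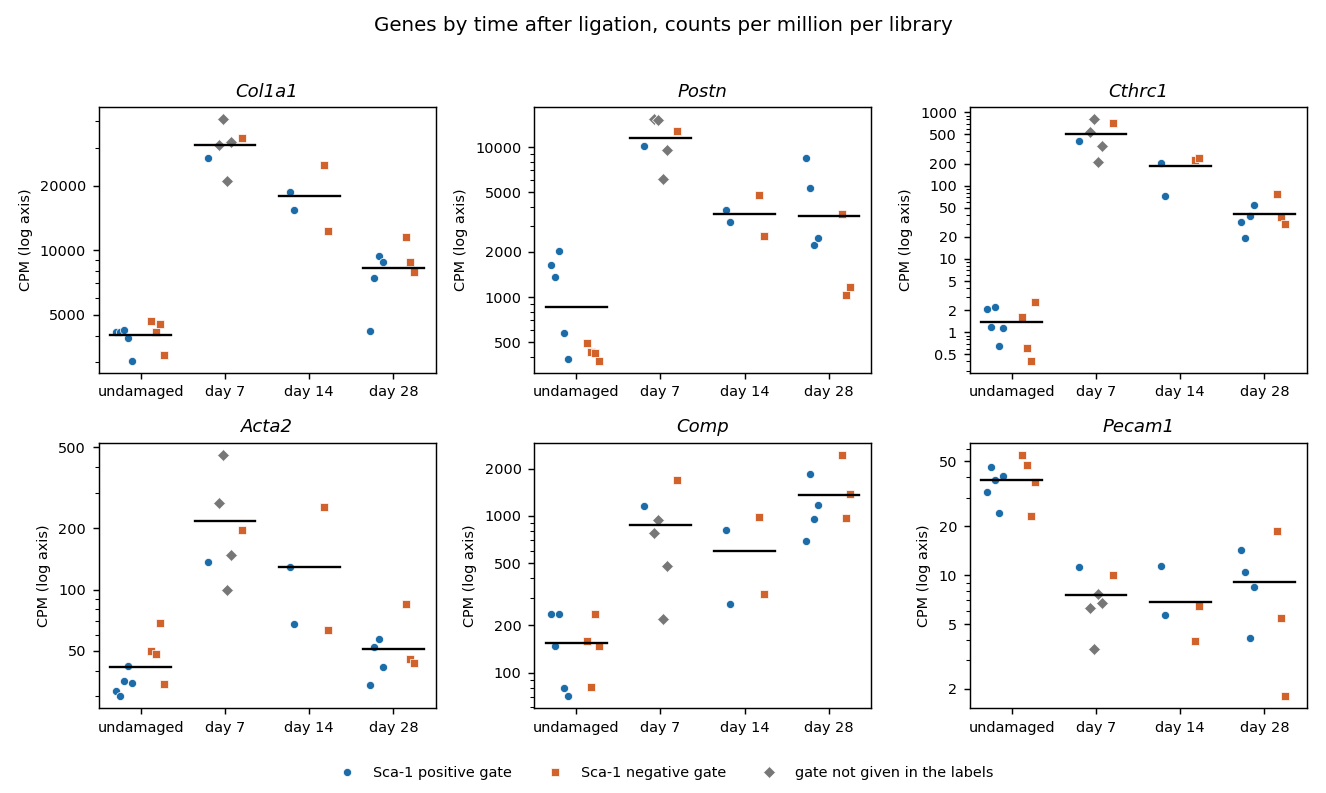
CPM (log axis) of Col1a1, Postn, Cthrc1, Acta2, Comp and Pecam1 in each library by time, with lines at the mean of each time point. Col1a1 averaged 4011, 30755, 17801 and 8280.0 CPM in undamaged hearts and at days 7, 14 and 28, and Acta2 averaged 41.6, 218, 129 and 51.3 CPM.

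At day 14 (4 libraries against 9, averaged over the gates), the matrix genes were still above undamaged levels. Cthrc1 was at 184 ± 76.0 CPM (6.96 ± 0.39 log2, adjusted p = 2.48e-09) and Col1a1 at 17801 ± 5409 CPM (2.13 ± 0.21, 2.33e-06). Collagens rose in 13 of 19 (14 adjusted over the list alone; adjusted p = 4e-23, and 0.0192 with an estimated correlation), with Col3a1 (2.09 ± 0.17), Col1a2 (1.80 ± 0.18) and Col8a2 (2.46 ± 0.27). Matricellular genes rose in 17 of 26 (18 adjusted over the list alone; 2.65e-25, and 0.0111 with an estimated correlation), with Fn1 (3.74 ± 0.36), Ddah1 (4.30 ± 0.36), Sparc (1.75 ± 0.16) and Postn (2.31 ± 0.40). Contractile genes rose in 12 and fell in 2 of 22 (12 and 2 adjusted over the list alone; adjusted p = 2.12e-08, and 0.0579 with an estimated correlation), such as Palld (3.70 ± 0.31), Actn1 (1.51 ± 0.16), Csrp2 (1.25 ± 0.18) and Acta2 (1.57 ± 0.27). Matrifibrocyte genes rose in 12 and fell in 1 of 24 (13 and 3 adjusted over the list alone; 4.64e-08, and 0.0777 with an estimated correlation). Among them were Runx1 (3.19 ± 0.37), Clu (4.36 ± 0.53), Cilp2 (4.18 ± 0.60) and Comp (1.93 ± 0.38, adjusted p = 0.0025). Comp missed the threshold without the negative (1.40, 0.0577) and without the positive replicate D1 (1.43, 0.0515). Wnt pathway genes rose in 9, with Wnt4 (4.35 ± 0.48), Wnt2 (3.25 ± 0.52) and Sfrp2 (2.69 ± 0.35), and fell in 1 of 29, Wif1 (-2.98 ± 0.51; 12 and 2 adjusted over the list alone; adjusted p = 1.69e-06, and 0.0579 with an estimated correlation).

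Proliferation genes rose in 9 of 35 at day 14 (16 adjusted over the list alone; adjusted p = 2.23e-09, and 0.0829 with an estimated correlation), with Kif23 (3.10 ± 0.60) and Bub1b (2.13 ± 0.44). Collagen processing genes rose in 7 of 21 (10 adjusted over the list alone; 1.83e-07, and 0.215 with an estimated correlation), with P4ha3 (4.71 ± 0.51), Plod2 (1.53 ± 0.19) and Lox (1.96 ± 0.28). Matrix proteases rose in 5, with Adam12 (4.27 ± 0.38), and fell in 1 of 25 (10 and 3 adjusted over the list alone; adjusted p = 0.0037, and 0.343 with an estimated correlation). Cardiac fibroblast identity genes fell in 5 and rose in 1 of 26 (9 and 2 adjusted over the list alone; adjusted p = 0.000719, and 0.115 with an estimated correlation). Lipid handling genes fell in 5 of 20, with the transcription factor Klf15 (-1.28 ± 0.21; 8 adjusted over the list alone; 4.6e-05, and 0.0579 with an estimated correlation). Early response genes fell in 4 of 26 (4 adjusted over the list alone; 8.75e-05, and 0.373 with an estimated correlation). With the code family as a covariate 0 were called, at a list median of still -0.56 log2. In prefixed libraries alone 1 was higher and 0 lower, at a median of -0.06. Adventitial genes rose in 6, with Mfap5 (1.27 ± 0.13), and fell in 2 of 28 (7 and 3 adjusted over the list alone) without a call for the list (adjusted p = 0.319). Chemokine genes rose in 5, with Cxcl13 (7.01 ± 1.11), the acute phase gene Saa3 (6.73 ± 1.09) and Il1rl1 (6.38 ± 1.20), and fell in 3 of 29 (0.946). TGF-beta and BMP pathway genes rose in 4, with Tgfb3 (1.52 ± 0.19), and fell in 5 of 30 (adjusted p = 0.879). Complement genes rose in 2 of 15, C2 (2.59 ± 0.43) and Clu (0.792). All day 14 libraries are prefixed. Within prefixed libraries alone, 9 of 29 chemokine genes were higher and 1 lower. Complement genes had 5 higher and 0 lower of 15 there, and interferon genes 5 and 0 of 35. The neuropeptide gene Nmb (-2.21 ± 0.27), Cyp2e1 (-3.77 ± 0.76), Rgcc (-2.20 ± 0.43) and Fmo2 (-2.12 ± 0.38) fell.

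Among cell type markers at day 14, epicardial ones rose in 9, with Wt1 at 48.1 ± 31.7 CPM (5.80 ± 0.61), and fell in 1 of 13 (10 and 2 adjusted over the list alone; adjusted p = 4.09e-08, and 0.084 with an estimated correlation). Endothelial ones fell in 4, with Pecam1 (-2.55 ± 0.46), and rose in 1 of 15, Erg (2.40 ± 0.38; 10 and 1 adjusted over the list alone; 0.000332, and 0.355 with an estimated correlation). All 3 adipocyte markers rose (3 adjusted over the list alone; adjusted p = 0.00973, and 0.231 with an estimated correlation). DESeq2 called 1 of them and the fit on prefixed libraries 0. Their member Adipoq was at 7.26 and 3.64 CPM in the negative and positive D9, and at 0 and 0.20 in D1. Without the libraries with Xist above 20 CPM 1 of the 3 was measured and edgeR did not call it, and 3 proliferation genes, 2 adventitial and 3 matrix protease genes were higher and 1 lipid handling, 1 endothelial and 0 early response genes lower. Without the 3 undamaged libraries with fewest genes 19 proliferation genes were higher, and 10 endothelial and 9 lipid handling genes lower. Cardiomyocyte markers fell in 1 of 15 (1 adjusted over the list alone; adjusted p = 0.00973, and 0.373 with an estimated correlation). Interferon (adjusted p = 0.896), glycolysis (0.0972), oxidative phosphorylation (0.212), macrophage (0.129), mural (0.166) and Schwann cell genes (0.879) were not called. By edgeR 825 genes were higher and 437 lower than in undamaged hearts, 904 and 331 within prefixed libraries. The count of 1262 was 620 without the negative replicate D1, 671 and 808 without the positive replicates D1 and D9, and 665 without the libraries with Xist above 20 CPM.

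**Figure D3:**
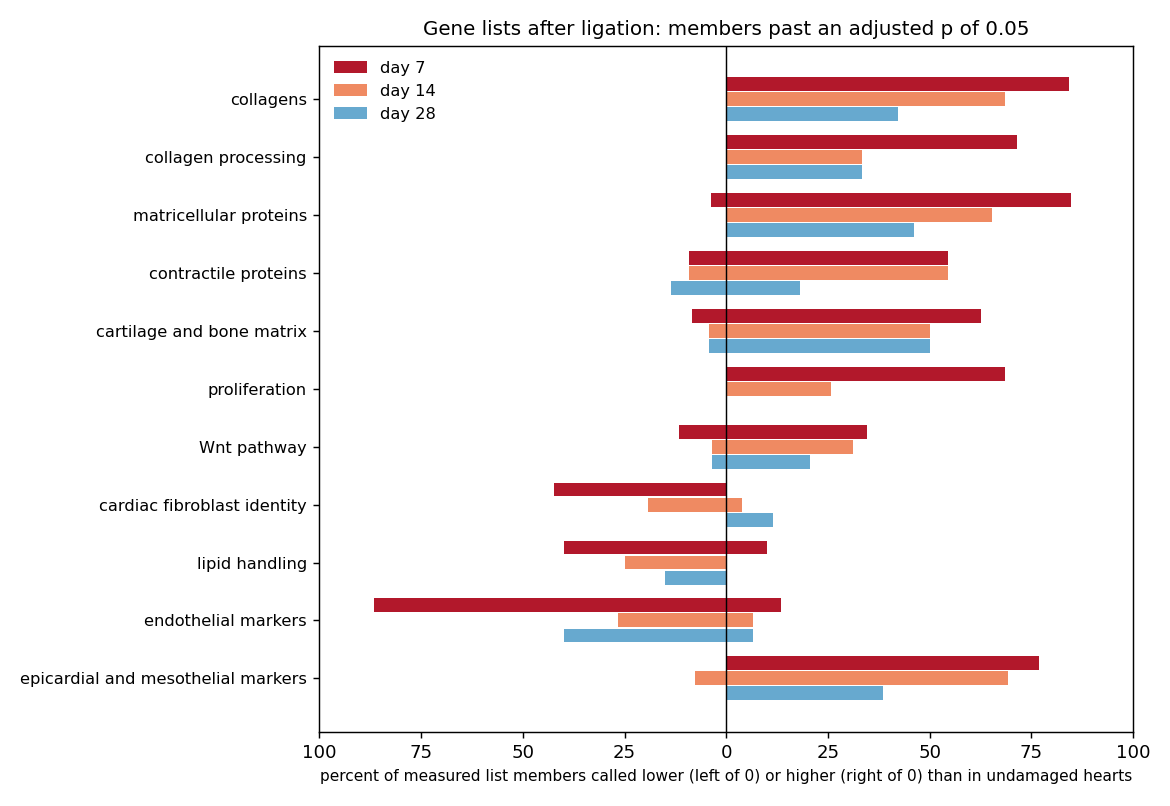
Percent of measured members of 11 gene lists called higher (right of 0) or lower (left of 0) than in undamaged hearts at days 7, 14 and 28; day 7 comes from the fit without the gate. Collagens had 16, 13 and 8 of 19 members called higher, and proliferation genes 24, 9 and 0 of 35.

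At day 28 (7 libraries against 9, averaged over the gates), cartilage and bone matrix genes stood above undamaged levels, as did Cthrc1 (41.3 ± 19.1 CPM, 4.87 ± 0.36, adjusted p = 2.47e-07). Matrifibrocyte genes rose in 12 and fell in 1 of 24 (18 and 3 adjusted over the list alone; adjusted p = 1.16e-16, and 0.0149 with an estimated correlation). Comp (ENSMUSG00000031849.9, chromosome 8, 70373558 to 70382066) was at 1353 ± 607 against 155 ± 69.1 CPM (3.13 ± 0.36, adjusted p = 3.26e-05), beside Cilp2 (4.87 ± 0.57), Fmod (3.16 ± 0.39) and Runx1 (2.97 ± 0.34). Matricellular genes rose in 12 of 26 (20 adjusted over the list alone; adjusted p = 1.6e-26, and 0.00775 with an estimated correlation), with Ddah1 (3.88 ± 0.33), Wisp1 (4.48 ± 0.60), Fn1 (2.30 ± 0.32) and Postn (2.04 ± 0.36). Collagens rose in 8 of 19 (11 and 1 lower adjusted over the list alone; 1.32e-12, and 0.102 with an estimated correlation), with Col8a2 (2.57 ± 0.25), Col3a1 (1.20 ± 0.15), Col1a2 (1.09 ± 0.16) and Col1a1 (1.04 ± 0.19). Collagen processing genes rose in 7 of 21 (8 adjusted over the list alone; adjusted p = 8.38e-07, and 0.347 with an estimated correlation), with P4ha3 (3.74 ± 0.47) and Lox (1.38 ± 0.25). Wif1 was at 0.158 ± 0.172 CPM against 50.2 ± 70.8 (-7.81 ± 0.64, adjusted p = 6.25e-07). The cytokine-like gene Cytl1 (-3.10 ± 0.29), Ahsg (-2.99 ± 0.41, and -1.41 in the prefixed libraries alone) and Enpp6 (-1.95 ± 0.28) fell.

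Contractile genes at day 28 had 4 higher, with Palld (2.41 ± 0.28) and Actn1 (1.06 ± 0.14), and 3 lower of 22 (4 and 3 adjusted over the list alone; adjusted p = 0.444). Acta2 was at 51.3 ± 16.7 CPM and not called. Wnt pathway genes rose in 6, with Sfrp2 (2.87 ± 0.32) and Sfrp1 (1.10 ± 0.14), and fell in 1 of 29 (10 and 1 adjusted over the list alone; adjusted p = 0.0124 upward, and 0.385 with an estimated correlation). The list had a median of 0.36 and a mean of -0.02 log2. TGF-beta and BMP pathway genes rose in 4, with Tgfb3 (1.29 ± 0.17), and fell in 1 of 30 (8 and 1 adjusted over the list alone; adjusted p = 0.0206, and 0.593 with an estimated correlation). Epicardial markers rose in 5 of 13, with Wt1 (4.14 ± 0.56; 9 and 1 lower adjusted over the list alone; 1.63e-07, and 0.138 with an estimated correlation). Endothelial ones fell in 6, with Pecam1 (-2.13 ± 0.37), Fabp4 (-1.98 ± 0.34) and Cdh5 (-2.06 ± 0.39), and rose in 1 of 15 (11 and 1 adjusted over the list alone; 7.56e-10, and 0.138 with an estimated correlation). Lipid handling genes fell in 3 of 20, with Cd36 (-2.19 ± 0.37; 4 adjusted over the list alone; adjusted p = 0.000754, and 0.138 with an estimated correlation). Cardiomyocyte markers fell in 1 of 15 (2 adjusted over the list alone; 0.0114, and 0.574 with an estimated correlation). Cardiac fibroblast identity genes had 3 higher of 26, including Ogn (0.94 ± 0.16) and Fbln1 (0.88 ± 0.15), without a call (adjusted p = 0.519).

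Several lists at day 28 moved apart between the code families. Chemokine genes had 2 of 29 higher with all libraries (4 adjusted over the list alone; adjusted p = 0.0121, and 0.636 with an estimated correlation). There were 16 lower in the letter-coded and 16 higher in the prefixed libraries alone. Early response genes had 1 higher and 5 lower of 26 (3 and 6 adjusted over the list alone; 0.00321, and 0.618 with an estimated correlation). There were 17 lower in the letter-coded, and 9 higher and 3 lower in the prefixed libraries. Interferon genes had 0 of 35 called by edgeR (3 lower by DESeq2, 6 without the 3 undamaged libraries with fewest genes; adjusted p = 0.000187 downward, and 0.593 with an estimated correlation), but 13 lower in the letter-coded and 3 higher in the prefixed libraries. Lipid handling genes had 12 lower in the letter-coded, and 5 higher and 3 lower in the prefixed libraries. Proliferation genes had 0 of 35 called by edgeR (2 higher by DESeq2, 3 without those 3 libraries; adjusted p = 0.0392 upward, and 0.618 with an estimated correlation). Adventitial (adjusted p = 0.525), complement (0.27, with C2 higher by 2.09 ± 0.39), matrix protease (0.105), glycolysis (0.249), oxidative phosphorylation (0.534), macrophage (0.252), mural (0.13, with Rgs4 higher by 2.07 ± 0.41), Schwann cell (0.519) and adipocyte lists (0.249) were not called. Of these, adventitial genes had 2 higher and 9 lower in the letter-coded, and 6 and 1 in the prefixed libraries. Complement (1 and 6, and 6 and 0), matrix protease (2 and 7, and 10 and 1) and glycolysis genes (0 and 9, and 5 and 1) parted as well. TGF-beta and BMP pathway genes had 4 and 5 (median -0.08 log2) in the letter-coded, and 9 and 0 (median 0.45) in the prefixed libraries, Wnt pathway genes 5 and 4, and 9 and 1, and mural genes 1 and 5, and 1 and 0. The letter-coded day 28 libraries hold 1 of the negative gate, E4. By edgeR 420 genes were higher and 229 lower with all libraries, 969 and 1293 with letter-coded and 957 and 398 with prefixed ones alone. The count of 649 was 371 without the negative replicate B6 of day 28.

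Between day 14 and day 28 (4 and 7 libraries) contractile and matrix genes fell. Contractile genes fell in 6 of 22, such as Tagln (-1.36 ± 0.22, adjusted p = 0.00238; 12 adjusted over the list alone; adjusted p = 5.9e-09, and 0.0845 with an estimated correlation). Collagens fell in 3 of 19, such as Col1a1 (-1.09 ± 0.23, 0.0126; 4 adjusted over the list alone; 6.11e-07, and 0.24 with an estimated correlation). Matricellular genes fell in 7 of 26 (4 higher and 9 lower adjusted over the list alone; adjusted p = 0.0038, and 0.61 with an estimated correlation), with Cthrc1 (-2.09 ± 0.36, 0.0036). Wnt pathway genes fell in 5 of 29 (2 higher and 7 lower adjusted over the list alone; 0.000246, and 0.154 with an estimated correlation), with Wif1 (-4.83 ± 0.73, 0.00168, not called by limma-voom) and Wnt2 (-2.77 ± 0.55, 0.00958). The protease Adam12 fell by 2.68 ± 0.40 (0.00168) and Clu by 3.30 ± 0.57 (0.00389). Nmb rose by 2.20 ± 0.27 (adjusted p = 0.000321; 8.95 ± 3.33 to 41.8 ± 26.4 CPM). Igfbp3, an insulin-like growth factor carrier, rose by 1.87 ± 0.35 (0.00709) and Dbp, a clock output gene, by 2.59 ± 0.48 (0.00597). Cardiac fibroblast identity genes rose in 4 of 26 (6 adjusted over the list alone; adjusted p = 2.89e-06, and 0.0845 with an estimated correlation). The 3 adipocyte markers fell by edgeR (3 adjusted over the list alone; 0.000246, and 0.154 with an estimated correlation), from levels that stood apart in the D9 replicates of day 14. DESeq2, the fit with the code family as a covariate and that on prefixed libraries each called 1 of them.

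Proliferation genes (0 of 35 called by edgeR, 1 lower by DESeq2, and 1 higher and 7 lower without the 3 undamaged libraries with fewest genes, adjusted p = 3.6e-07 downward, and 0.154 with an estimated correlation), TGF-beta and BMP pathway genes (4 higher and 2 lower of 30, 0.02, and 0.61 with an estimated correlation), interferon (0.00135 downward, and 0.664 with an estimated correlation) and chemokine genes (0.0431 upward, and 0.792 with an estimated correlation) also passed the preset test between days 14 and 28. Within prefixed libraries alone, 14 of 29 chemokine genes were higher and 1 lower, and 11 of 26 early response genes were higher and 2 lower. With the code family as a covariate these counts were 2 and 3, and 1 and 2. By edgeR 202 genes were higher and 205 lower at day 28 than at day 14, 544 and 319 within prefixed libraries. The count of 407 was 114 and 186 without the negative replicates D1 and D9 of day 14, 181 and 100 without the positive ones. It was 158 and 161 without the negative replicates B4 and B6 of day 28, and 87 without the libraries with Xist above 20 CPM. In the last of these Wnt2 (-2.57, adjusted p = 0.140) and Dbp (2.50, 0.112) were not called, and 1 collagen, 2 matricellular and 2 Wnt pathway genes were lower and 0 identity genes higher. Dbp also missed the threshold without the positive D9 (2.47, 0.0581), Igfbp3 without the negative D1 (1.66, 0.0647). Without the negative and the positive D1 so did Col1a1 (-0.80, 0.143; -1.01, 0.0634) and Clu (-2.20, 0.0579; -2.10, 0.0512).

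From day 7 to day 14 (6 and 4 libraries) edgeR called 2 genes, both higher at day 14: S100a1 (1.54 ± 0.26, adjusted p = 0.0381; 21.4 ± 4.39 to 63.3 ± 31.1 CPM) and, named after its value was seen, the growth factor Fgf10 (3.25 ± 0.58, 0.044; 1.08 ± 0.645 to 10.5 ± 8.00 CPM, 6.73 without the positive D9). At an unadjusted p under 0.05 there were 1217, where 669.6 are expected by chance. DESeq2 called 61 higher and 72 lower and limma-voom 41 and 52. Lists fell without a member called over all genes by edgeR: collagens (12 lower adjusted over the list alone; adjusted p = 5.41e-14, and 0.1 with an estimated correlation), collagen processing (8; 1.39e-09, and 0.133 with an estimated correlation) and matricellular genes (6; 1.28e-09, and 0.1 with an estimated correlation). So did contractile (0.00339), proliferation (0.0015) and macrophage genes (4.81e-05). Wnt pathway (7 higher adjusted over the list alone; adjusted p = 0.00304, and 0.149 with an estimated correlation), adventitial (0.0012), identity (0.0115), complement (0.0107) and oxidative phosphorylation genes (4.81e-05) rose. None of the 11 calls held with an estimated correlation (at least 0.1). By DESeq2, 6 collagens, 2 collagen processing, 3 matricellular and 1 contractile genes were lower over all genes, and 2 Wnt pathway, 1 adventitial and 1 complement genes higher. S100a1 and Fgf10 were both uncalled without any one of the undamaged negative replicates E5 and F3, the undamaged positive A6, the labelled day 7 libraries, the unlabelled 1A and 1B, the positive D1 of day 14 and the day 28 replicates B4 (positive) and B6 (negative). Fgf10 was also uncalled without 4B and the positive D9. The count moved by more than 1.5 times without any one of 22 of the 26 libraries, from 0 to 44 (without the unlabelled 4A), and was 0 without the libraries with Xist above 20 CPM.

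Within single gates, genes of the response to ligation were called in both gates. Cthrc1 rose by 6.53 ± 0.52 in the positive (adjusted p = 4.74e-07) and 7.40 ± 0.59 in the negative gate (1.08e-06) at day 14, Col3a1 by 2.14 ± 0.23 and 2.04 ± 0.24, and Col1a1 by 2.11 ± 0.29 and 2.15 ± 0.31. At day 28 the rises were 4.61 ± 0.46 and 5.13 ± 0.54 for Cthrc1, 2.93 ± 0.47 and 3.33 ± 0.54 for Comp, 2.69 ± 0.45 and 3.25 ± 0.52 for Runx1, 2.27 ± 0.33 and 2.88 ± 0.37 for Col8a2. Cytl1 differed by -2.80 ± 0.37 and -3.40 ± 0.45. Mfap5 rose in the negative gate (1.19 ± 0.17, adjusted p = 0.00131) and differed by 0.32 ± 0.15 in the positive gate (0.352) at day 28. The difference between gates was not called as an interaction. The gates shared 155 higher and 31 lower genes at day 14 (6.70 and 0.347 for independent lists) and 61 and 9 at day 28 (1.16 and 0.0812). The libraries share replicate codes between the gates and are not independent, so part of the excess may come from them. Of all genes, 74.3% had one sign in both gates at day 14 and 60.7% at day 28. Held with an estimated correlation at day 14 were collagens in the positive (7 of 19 rose, 13 adjusted over the list alone; adjusted p = 0.0136 with an estimated correlation) and negative gate (9 and 12; 0.0402). So were matricellular genes in the positive (10 of 26, 16 adjusted over the list alone; 0.0136) and negative gate (15 and 17; 0.0204). In the positive gate contractile (5 of 22; 0.0443) and Wnt pathway genes (5 of 29; 0.0279) held, and in the negative gate lipid handling genes downward (2 of 20, 9 adjusted over the list alone; 0.0376). At day 28 these were matricellular genes (6 of 26 positive, 10 negative; 0.0354 and 0.0233) and matrifibrocyte genes (7 and 9 of 24; 0.0354 and 0.0419).

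By edgeR the day 14 counts were 222 higher and 34 lower in the positive and 417 and 141 in the negative gate, and the day 28 counts 142 and 33, and 113 and 34. The day 14 positive count of 256 was 83 and 146 without its replicates D1 and D9. The negative count of 558 was 117 and 335 without D1 and D9 and 360 without the undamaged F3. The day 28 positive count of 175 was 78 without B6 and 87, 85 and 111 without the undamaged replicates E1, E3 and A6. The negative count of 147 was 62 and 64 without E4 and B6 and 91 without the undamaged F3. Adventitial genes in the negative gate at day 14 had an upward call (adjusted p = 0.0161, and 0.415 with an estimated correlation) with a median of -0.03 and a mean of 0.23 log2.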

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

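The tests of epicardial markers, clock genes and early response genes below, the splits that keep the code pairs, and the other splits of the samples except those of day 28 against day 14, day 7 against undamaged, day 14 against day 7 and the day 28 interaction, were chosen after the result was seen.

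In 3 of 60 sets of values a library of an undamaged group stood far from the others, and chance gives about 1 in 20, here 3. Col1a1 was 3060.3 CPM in the positive replicate B7 (3908 to 4234 in the other 4 positive libraries), and Thy1 was 127 CPM in the positive replicate A6 (58.6 to 72.7 in the others). Gene counts were 10.9 M in the negative replicate A6 (14.7 to 15.2 M in the others).

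Letter-coded and prefixed libraries of the same time point and gate differed: with the gate in the model, 1179 genes were higher and 582 lower in letter-coded undamaged libraries, and 231 and 448 in letter-coded day 28 ones (1 of their 3 libraries negative), with 275 called in opposite directions and 19 in the same. A single offset shared by all prefixed libraries is argued against by the correlation of the differences in undamaged hearts and at day 28 (r = -0.143). The prefixed undamaged and day 28 libraries carry different numbers before their codes, so an offset tied to the number was not tested. Transcripts lost from the undamaged prefixed libraries cannot be told apart from other sources: 67.0% of the genes called were lower there, under the bound of 70% set before the result, but TMM scaling centres the differences and so made that bound wrong, and these libraries held 12325 to 14142 detected genes at TMM factors of 1.09 to 1.19, against 14774 to 15309 genes and 0.911 to 0.978 in letter-coded ones. Early response genes, which cell dissociation induces, had 16 of 26 members such as Atf3 and Myc higher in letter-coded undamaged libraries and 15 lower in letter-coded day 28 ones, 12 of them in both, although Fos (0.77 log2) and Jun (0.81) were called higher in letter-coded day 28 libraries. Other lists turned alike, with 17 higher then 15 lower of 29 chemokine genes. Of 15 complement genes there were 8 then 5, and of 18 glycolysis genes 9 then 5. The pattern is thus not particular to early genes, and a dissociation response of differing strength is a candidate explanation that stays open. No biological one was tested, as the labels part the families only by their codes and the numbers before them.

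Epicardial and mesothelial markers rose after ligation, although the sort kept only GFP positive cells without CD45 and CD31, a gate that would remove mesothelial cells lacking Pdgfra. Of Msln, Upk3b, Upk1b, Krt19, Krt8, Krt18 and Lrrn4, 6 were called higher at day 14 or day 28, so mesothelial cells carried into the sort may be a source of these transcripts, at mean levels at day 14 of 8.76 ± 8.93 CPM for Krt19 and 15.9 ± 14.5 CPM for Lrrn4 (4.44 and 9.27 without the negative D1). To test the same cells as the only source of Wt1, the Sca-1 positive minus negative difference was compared over 4 code pairs. That of Wt1 exceeded the median of those markers by 1.27 log2 on average (SD 0.634). It lay above each of the 7 markers in every pair, by 0.0515 log2 over the highest marker in B6 and 1.77 in B4 (day 28). Markers of a pair are not independent, so the pairs are the unit. An exact two-sided test that flips the signs of the 4 pair differences gave p = 0.125, the smallest it can give, and so cannot decide this question. The bound set for the excess of Wt1 over the markers was rewritten after the value was seen, and 1 of the 13 markers (Rspo1) is also a Wnt pathway gene. Carried-over cells as the only source or a part of it, or with more Wt1 in the positive gate, and expression of Wt1 in Pdgfra positive cells after ligation stay open.

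Clock genes differed between day 28 and day 14: 7 of 10 genes of the output and repressor limb, such as Dbp (2.59 log2) and Per3 (1.83), were higher at day 28, and 0 of the 5 genes set against them were called by edgeR, the activators Arntl (-0.77), Npas2 (-1.07) and Clock (-0.14) and the repressors Nfil3 (1.08) and Cry1 (0.07). The mean of the 10 exceeded that of the 5 by 1.86 log2 and that of the 3 activators by 2.35, so collection at another phase of the day cycle may be the source, although these sets were chosen after the result was seen. Against the day 28 library with most reads outside genes as the source, 7 genes were still called without it, and against the letter-coded day 28 libraries, 7 kept their sign and a difference of at least 0.5 log2 among prefixed libraries. Without the libraries with Xist above 20 CPM 1 of the 10 was called, with a median of 1.68 log2. Against undamaged hearts and without E2, the library with most reads outside genes, the 10 had 0 higher and 6 lower at day 14 (median -0.87 log2). At day 28 they had 1 higher and 0 lower (0.54). With the code family as a covariate these counts were 0 and 2 (-0.63), and 5 and 0 (0.73). The difference is therefore not placed at day 28 alone. The labels give no time of collection, and a biological shift of the clock after ligation was not tested.

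Other splits of the samples were fitted to see if chance alone could give the counts. For the gate in undamaged hearts 2 of 100 splits gave as many genes as the real 428, the other being the split of letter-coded from prefixed libraries with 1083, which points to a structure of the samples. The value with the code pairs as a block was 308 higher and 240 lower, and the 19 splits that part as many pairs are too few for a share under 0.05 (real 428, highest other 2). For the gate at day 28, 2 of 35 splits gave as many as the real 82, so by this count chance is not excluded. The other was again letter-coded against prefixed, with 614, which points to the same structure, and blocked by code pairs the gates gave 57 higher and 36 lower. The 12 splits that part as many pairs are too few for a share under 0.05 (real 82, highest other 2).

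Among splits that ignore the code pairs, 1 of 100 was as large, the real one, for day 14 against undamaged (real 1262, highest other 134), day 28 against undamaged (real 649, highest other 356), day 28 against day 14 (real 407, highest other 38) and day 7 against undamaged (real 3048, highest other 751), which excludes chance only where libraries of a code are independent. Of splits that keep the code pairs, 10 exist for day 14 against undamaged (real 1262, highest other 1474) and 6 for day 28 against day 14 (real 407, highest other 871), too few for a share under 0.05. For day 28 against undamaged 2 of 100 such splits were as large (real 649, highest other 1603). The highest of these 3 set the prefixed undamaged libraries against day 14 and letter-coded undamaged ones, those with letter-coded day 28 libraries against the rest, and the prefixed day 28 libraries against day 14 and letter-coded day 28 ones, which points to the structure by code family. Within a gate no code pairs arise. For day 28 against undamaged only the real split was as large in the positive (1 of 100, real 175, highest other 24) and negative gate (1 of 35, real 147, highest other 15). This excludes chance only where these libraries are independent, which the labels do not say. The split of day 28 against undamaged with 356 genes exchanged letter-coded libraries between the groups. For day 14 against day 7, 4 of 100 splits were as large (real 2, highest other 31), a split calling several times the real count, which points to a structure of the samples. For the day 28 interaction the real count was 0, so all 100 of 100 splits were as large (highest other 100) and the comparison says nothing.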

How the results depend on the processing

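The fits without the 3 undamaged libraries with fewest genes, without the library with most reads outside genes (E2) and without the libraries with Xist above 20 CPM, and those of letter-coded libraries for the gate at day 28 and of prefixed ones for day 28 against day 14, were added after seeing the data. Of 200 pairs of a named gene and a comparison, 0 changed direction and 153 kept their call in every setting run. Genes whose sign and call held were preferred for the text. These counts, and those of single calls below, therefore do not measure how stable calls are in general. Lists did turn between code families, such as chemokine genes at day 28 (16 lower in letter-coded, 16 higher in prefixed libraries). Leaving out 1 library left the call as it was in 4235 cases and ended it in 53, and other settings did so in 2732 and 61, with 5 gained. Except where stated, the cause was not tested. Counts below are totals of genes called, each against its count with all libraries. Depth limits genes near 3 counts, 0.0583 to 0.416 CPM per library.

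DESeq2 called 824 for the gate in undamaged hearts (428), 33 at day 14 (7), 404 at day 28 (82), 1122 for day 28 against undamaged (649), 764 for day 28 against day 14 (407), 418 and 862 for day 14 in the positive (256) and negative gate (558), 434 and 436 for day 28 in these (175 and 147), 2 and 4 for the interactions at days 14 and 28 (0 and 0) and 133 for day 14 against day 7 (2). Limma-voom called 25 and 32 for the gate at days 14 and 28, 416 and 898 for the single gates at day 14, 66 and 82 at day 28, and 93 for day 14 against day 7. The test beyond 1.5-fold, stricter by construction, called 125, 4 and 25 for the gate in undamaged hearts and at days 14 and 28, 491 for day 14 and 182 for day 28 against undamaged, 41 for day 28 against day 14, 136 and 257 (day 14) and 53 and 45 (day 28) in the single gates, 819 for day 7 against undamaged and 0 for day 14 against day 7. Without a low-count filter the gate at day 14 had 12, its interaction 1 and day 14 against day 7 had 7, which had 9 at a mean CPM of 5 or more and 13 with upper-quartile factors.

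With only the groups compared, which have fewer libraries, the gate had 271 (undamaged) and 42 (day 28), the negative gate 140 (day 14) and 50 (day 28), the positive gate 93 (day 28) and day 14 against day 7 had 45. With the code pairs as a block the gate at day 14 had 52. The block, run for the gate and its interactions only, changed no other count by more than 1.5 times. Prefixed libraries alone gave 212 and 25 for the gate in undamaged hearts and at day 28, 1355 for day 28 against undamaged and 863 for day 28 against day 14. Letter-coded libraries alone gave 2262 for day 28 against undamaged and 24 for the gate at day 28, where 1 negative library (E4) has no spread of its own and borrows that of the other letter-coded groups, so the 24 says nothing of the gate. With only the labelled gates of day 7 there were 1196 genes against undamaged and 45 at day 14 against day 7.

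Without the 3 undamaged libraries with fewest genes the gate had 253, 18 and 340 in undamaged hearts and at days 14 and 28. Day 14 and day 28 against undamaged then had 2287 and 1274, day 28 against day 14 had 1060, the positive gate 520 (day 14) and 378 (day 28), and day 14 against day 7 had 133. Without E2 the gate at day 28 had 53 and day 14 against day 7 had 8. Without the libraries with Xist above 20 CPM, which leaves 1 library per gate at day 14 that is assumed to vary like the other groups, there were 0 for the gate at day 14, 665 for day 14 against undamaged (146 and 289 in the positive and negative gate), 87 for day 28 against day 14, 880 for day 7 against undamaged and 0 for day 14 against day 7.

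Leaving out 1 library in turn, the gate ran from 265 to 503 in undamaged hearts, 0 to 10 at day 14 and 18 to 155 at day 28. Day 14 against undamaged ran from 620 to 1452, day 28 from 371 to 738, day 7 from 2354 to 3331, day 28 against day 14 from 100 to 519 and day 14 against day 7 from 0 to 44. In the positive and negative gate the ranges were 83 to 315 and 117 to 687 at day 14, and 78 to 241 and 62 to 201 at day 28, and for the interactions 0 to 1 and 0 to 0.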

Other observations

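Markers of other cell types were also read per library. Adipoq, an adipocyte gene, was at 7.26 and 3.64 CPM in the negative and positive day 14 replicates D9, at 0.2 CPM in the positive and 0 in the negative D1, and at 1.72 CPM in the day 7 library 4A. In the day 7 libraries without a labelled gate, Ly6a was at 297 CPM in 1A, 36.1 in 1B, 329.9 in 4A and 31.2 in 4B. Lymphoid and erythroid lists had 1 measured member each, Cd79a and Alas2, and edgeR called neither. Alas2 was called lower at day 28 than in undamaged hearts by DESeq2 (-3.63 log2) and without the 3 undamaged libraries with fewest genes (-4.07), and at day 7 without these (-2.46) and against letter-coded undamaged libraries (-2.69). The first 3 principal components of 11402 genes held 26.9%, 13.5% and 10.6% of the variance.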
